A study of Mus musculus with 12 samples.

How the data were processed

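The series measured RNA from mouse colon by sequencing. Its 12 samples fall into 3 groups of 4 by their treatment label: control, DSS and FGF1. DSS is dextran sulfate sodium, a detergent-like polymer given to mice to injure the colon lining. FGF1 is fibroblast growth factor 1, and the design text speaks of giving the recombinant protein to mice with bowel inflammation. The labels do not say whether the FGF1 mice also received DSS, nor the dose or duration of either. Per the labels, libraries were made from 5 µg of total RNA with oligo(dT) beads.

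Per the submitters' processing notes, the tools were cutadapt 1.9, HISAT2 2.0.4, StringTie 1.3.4d and edgeR, with genome build GRCm38. The version of edgeR and the role of each tool are not given in the sources used here. For each library the authors deposited a list of transcript structure events (transcription starts and ends, skipped exons, retained introns and other forms), each with its position, the transcript it belongs to and that transcript's FPKM (fragments scaled for transcript length and for the library's total). The deposited FPKM values were used without further scaling. A second deposited number per event held the same placeholder in every library and was not used. Over all libraries, 187383 rows, each an event in a given transcript, belonged to 74659 transcripts of 22377 genes. Gene symbols and gene coordinates came from the GENCODE vM21 annotation of GRCm38, in which 22330 of the gene identifiers had a symbol and 47 did not.

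The files list only transcripts that enter an event, so a gene's value can leave out some of its RNA. Of the 101669 annotated transcripts of the listed genes, 72.8% were listed. Only 8 of 26787 annotated single-exon transcripts were listed, so Atoh1, a single-exon gene, has no value. The main transcript of Gapdh was not listed either. A transcript absent from a library's list was given 0 there, which can mean absence or a failed assembly. FPKM values hold no read counts. Steps between the lowest values implied about 16700000 to 22800000 fragments per library, but only 27.5% to 38.8% of low values lay within 0.05 of a whole step, so reads were not recovered and no count model was run. All expression values are FPKM, and their counting error is not known.

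The design, the 28 gene lists, the rule for named genes and 61 alternatives were fixed before the data were examined. One part of that design was changed. It defined a gene's FPKM as the sum over the gene's start events, on the premise that each transcript has a start event in each library. The files contradicted the premise: 27.6% of 614130 listed transcript values had no start event in that library, 9033 transcripts had a start event in some of their libraries and not in others, and start events held 74.8% to 77.1% of the FPKM of a library. In 3594 of 12578 tested genes (28.6%), the start-event sum was under 0.5 of the transcript sum in some libraries and not in others. The gene value used here is the sum over all listed transcripts of the gene, each taken once. This was decided from the files' structure before any comparison of groups was run. Counts from the start-event values are printed beside each main count, because several are much lower.

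Genes were tested in R 4.3.3 with limma 3.58.1 (empirical Bayes with a mean-variance trend, two-sided) on log2(FPKM + 1). A single model was fitted to all 12 libraries, so that the 3 groups share their estimate of the spread. Genes with an FPKM of at least 1 in at least 4 libraries were kept. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, and a gene was called at an adjusted p under 0.05. A log2 fold change on this scale understates the change of genes with low FPKM. Unless stated otherwise, errors of levels are SDs over 4 libraries and errors of log2 fold changes are SEs.

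Gene lists were tested with camera in limma, with a preset correlation between genes of 0.01 and Benjamini-Hochberg adjustment over the lists of a comparison. The same test with a correlation estimated from the residuals stands beside it; no list was called with it in any comparison. The lists cover goblet cells, crypt base stem cells, the cell cycle, absorptive colonocytes, enteroendocrine cells, tuft cells, deep crypt and antimicrobial genes, cell junctions, cytokines, neutrophils, monocytes and macrophages, T and NK cells, B and plasma cells, mast cells and eosinophils, fibroblasts and matrix, smooth muscle, endothelium, enteric neurons and glia, adipocytes, other tissues (pancreas, liver, skeletal muscle and blood), FGF signalling, Notch, Wnt, interferon-stimulated genes, endoplasmic reticulum stress, mitochondrial respiration, PPAR targets with lipid handling, and fetal-like epithelial repair. The neutrophil list had 2 members that passed the FPKM filter and the mast cell and eosinophil list 1, under the 3 needed for the list test. A list score is the mean log2(FPKM + 1) of the tested members in a library. Explanations that rest on scores were tested on it and on a second score, the mean log2(FPKM + 0.1) of the members with a mean of at least 5 FPKM in control, and groups were taken as apart only where both scores had no overlap, a rule set after the values were seen.

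Genes are named by a fixed rule. In each comparison these are the 10 largest increases and 10 largest decreases among called genes whose groups do not overlap and whose mean is at least 5 FPKM in the higher group, without predicted, clone, ribosomal, mitochondrial, immunoglobulin or T cell receptor segment names. Added to these are up to 4 called members per list with the smallest adjusted p, and always Fgf1, Fgfr2, Atoh1, Muc2, Lgr5 and Spdef. Where under 10 genes passed, the 5 smallest unadjusted p in each direction are named as not passing. All called genes of such a comparison are named too, which goes beyond the fixed rule. Some genes that meet the rule are not reported here.

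Splicing was tested with limma on log2((A + 0.5)/(B + 0.5)), where A and B are the FPKM of the forms of an event, for exon skipping, intron retention, start sites and end sites. Events needed a mean of at least 5 FPKM and a mean share between 0.05 and 0.95. Numbers of listed events per library were compared with an exact permutation test (two-sided, 4 against 4, smallest possible p 0.0286).

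The steps were tested on simulated data with 200 changed genes. Of genes changed 2-fold, 61.7% were recovered in DSS against control, 60.9% in FGF1 against DSS and 64.3% in FGF1 against control, and of genes changed 1.5-fold, 35.1%, 33.8% and 29.6%. False calls were 6.9%, 6% and 0.8% of all calls. For DSS against control, recovery of 4-fold changes was 22.9% for exon skipping, 66.7% for intron retention, 50% for start sites and 61.5% for end sites. A simulated shift of the goblet list brought no other list to a call. The simulated genes varied independently, whereas the estimated correlation in the data was 0.722 for the fibroblast list and 0.905 for the smooth muscle list. The simulation therefore does not test the preset correlation. Recovery after adjustment also depends on how many genes change and by how much. The shares recovered thus hold for 200 changed genes and are not the power of the real comparisons. Those with FGF1 gave 7 calls against DSS and 10 against control, which cannot be read as few changes.

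The alternatives comprised a pseudocount of 0.1, no filter, a mean of at least 5 FPKM, median-of-ratios scaling, scaling each library to the same sum, gene values from end events or from the largest event, the replicate number as a block, only the 8 samples of the groups compared, a robust fit, sample weights and leaving out each library in turn. A further 24 alternatives were chosen after seeing the data. They are the start-event values, transcripts listed in all 12 libraries, genes with 1 annotated transcript, the smooth muscle score as a covariate, and fits without control 3 and FGF1 3 (the highest smooth muscle scores) or without DSS 3 and DSS 4 (the fewest listed transcripts). Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6 read the files, and matplotlib 3.10.9 drew the plots. A deposited table of event numbers was not used, because the numbers were counted from the event lists.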

Results

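Messenger RNA of mouse colon was sequenced in 12 libraries, 4 from control mice, 4 from the DSS group and 4 from the FGF1 group. DSS, a polymer that injures the colon lining, serves as a model of ulcerative colitis. FGF1 is a secreted growth factor, and per the design text the question was whether supplying it acts on the colon of mice with bowel inflammation, in particular on the step from stem cell to goblet cell. The implied depth ran from 16700000 fragments (DSS 1) to 22800000 (control 1). A library listed between 45795 (DSS 3) and 54313 transcripts (control 3), with means of 53336 ± 831 in control, 49182 ± 2970 in DSS and 51015 ± 859 in FGF1 (SD, n = 4 each). Between 11190 and 12721 genes reached 1 FPKM, and the 10 most abundant genes held 5.6% (control 3) to 9.9% of a library's FPKM. The labels do not say that the samples came from separate animals, so every p-value measures only the spread between these samples.

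Libraries of a group resembled each other more than libraries of control and DSS did. The median Spearman correlation over genes was 0.958 within control, 0.952 within DSS and 0.957 within FGF1. It was 0.921 between DSS and control, 0.947 between FGF1 and control and 0.951 between FGF1 and DSS. The mean log2 level of the smooth muscle genes was highest in control 3 (7.12) and FGF1 3 (6.84), against 5.44 to 6.56 in the other controls and 4.37 to 5.79 in the other FGF1 libraries. The same score was 5.10, 4.94, 4.37 and 3.57 in DSS 1 to DSS 4. Fibroblast genes scored 1.69 in DSS 3 and 1.41 in DSS 4, against 3.04 in DSS 1 and 2.44 in DSS 2.

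The comparison of DSS with control asks how the treated colon differed from the untreated one. Col3a1, a fibrillar collagen of connective tissue, fell from 66.8 ± 13.7 FPKM in control to 8.79 ± 7.12 in DSS (SD, n = 4 each; log2 fold change -3.06 ± 0.46, SE, adjusted p = 0.00368). Igha, the constant region of immunoglobulin A, fell from 1050 ± 646 to 59.9 ± 31.5 (log2 fold change -4.10 ± 0.51, adjusted p = 0.00246), and Jchain, which joins immunoglobulin A into dimers, from 194 ± 100 to 7.27 ± 5.74 (-4.65 ± 0.62, adjusted p = 0.00317). The Jchain call ended under 3 of 24 alternatives, none of them the omission of 1 library. Over all alternatives Jchain ran from -5.06 to -1.29 (limma, adjusted p up to 0.134). Slc9a3, the sodium-proton exchanger of the absorptive brush border (chromosome 13, 74121457 to 74169442, GRCm38), rose from 29.9 ± 5.35 to 142 ± 46.3 (2.17 ± 0.21, adjusted p = 5.06e-04), and Saa3, an acute-phase protein, from 11.3 ± 6.46 to 96.4 ± 39.0 (3.05 ± 0.53, adjusted p = 0.00567). Muc2, the gel-forming mucin of goblet cells (chromosome 7, 141690340 to 141754693), fell from 4169 ± 1200 to 1988 ± 464 (-1.06 ± 0.25, adjusted p = 0.0189), a call that ended without control 4 (adjusted p = 0.0585), with no filter on low genes (0.0987) and with start-event values (-1.26, adjusted p = 0.202; range over the alternatives 0.0119 to 0.202).

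**Figure D1:**
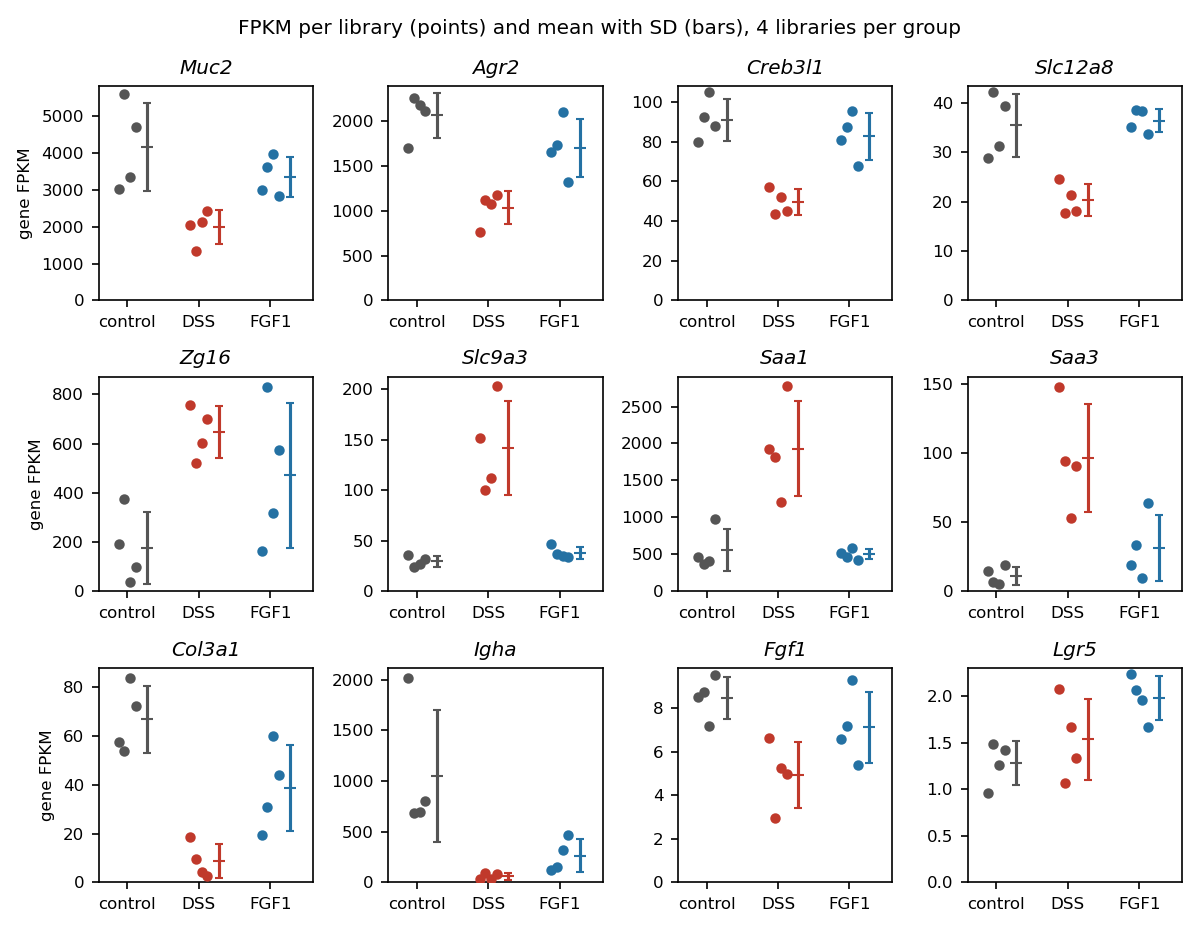
FPKM of 12 named genes in each library (points, 4 per group) with the group mean and SD, on a vertical axis of FPKM. Col3a1 averaged 66.8 in control, 8.79 in DSS and 38.7 in FGF1, and Slc9a3 averaged 29.9, 142 and 38.0.

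Among the largest increases in DSS was the anion channel gene Best2 (0.837 ± 0.913 to 8.08 ± 3.14 FPKM, adjusted p = 0.0107). Its call ended under 3 of 23 alternatives, with log2 fold changes of 0.93 to 3.5 over all of them (adjusted p up to 0.234). BB123696 went from 0.2 ± 0.224 to 17.5 ± 13.1 (adjusted p = 0.00468). The metallothioneins Mt2 (log2 fold change 2.66) and Mt1 (2.01) rose too, but without DSS 3 their adjusted p was 0.0529 and 0.0553. Zg16, a goblet cell lectin, rose by 2.27 ± 0.61, from 177 ± 146 to 645 ± 106 FPKM, with adjusted p up to 0.0864 when control 3, control 4, DSS 1, DSS 3 or DSS 4 was left out. Lhfpl2 (2.76) lost its call without control 2, control 4, DSS 2, DSS 3 or DSS 4 (adjusted p up to 0.0665), and its start-event value was -0.76. Slc51a, a bile acid transporter subunit (2.00), lost its call without control 3, control 4, DSS 3 or DSS 4 (adjusted p up to 0.0655). Among the largest decreases were Gsdmc4 (431 ± 142 to 37.1 ± 47.9 FPKM), Gsdmc2 (443 ± 228 to 50.8 ± 40.9) and Gsdmc3 (123 ± 57.4 to 15.2 ± 11.3), with adjusted p from 0.00505 to 0.00762. Clec3b (-3.02), Ccl21a, a lymphocyte-attracting chemokine (-2.96), and Dpt, a matrix protein (-2.94), fell as well, and kept their call whichever library was left out. The Gsdmc, Saa, Mt and immunoglobulin genes each have near-identical relatives, so the assignment of fragments among them is uncertain.

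Epithelial lists moved in different directions in DSS. Of 26 absorptive colonocyte genes tested, 4 rose (5 adjusted over the list alone) and none fell, among them Slc9a3, Saa1 (558 ± 283 to 1932 ± 645 FPKM) and Guca2b, which encodes uroguanylin (29.0 ± 4.46 to 77.9 ± 28.8). Guca2b lost its call under 2 of 24 alternatives, with log2 fold changes of 0.467 to 1.52 over all of them (adjusted p up to 0.27). The colonocyte list had a median log2 fold change of 0.19 (adjusted p = 1.37e-04, and adjusted p = 0.41 with an estimated correlation). Of 25 goblet genes, 2 rose (3 adjusted over the list alone) and 6 fell (6), with a median of -0.29 and adjusted p = 0.254, so the list was not called. Its falling members included Agr2, a disulfide isomerase needed for mucin folding (2069 ± 249 to 1034 ± 186 FPKM, adjusted p = 0.007), Creb3l1 (91.2 ± 10.6 to 49.7 ± 6.41, adjusted p = 0.00368) and Slc12a8 (35.4 ± 6.34 to 20.4 ± 3.23, adjusted p = 0.00673). Of 13 tuft cell genes, 3 fell (5 adjusted over the list alone), including the kinase gene Dclk1 (-1.28) and Rgs13 (-0.79), with a list median of -0.53 (adjusted p = 0.00109, and adjusted p = 0.41 with an estimated correlation). Rgs13 pointed the other way with end events (0.975), and Dclk1 lost its call under 3 of 22 alternatives (adjusted p up to 0.2). Of 18 crypt base stem cell genes, 3 fell (3 adjusted over the list alone), among them Tnfrsf19 (2.01 ± 0.273 to 0.604 ± 0.191 FPKM, adjusted p = 0.00337), and the list was not called (median -0.12, which turned positive with median-of-ratios scaling, adjusted p = 0.424). The stem cell receptor Lgr5 was at 1.28 ± 0.238 FPKM in control and 1.54 ± 0.434 in DSS (adjusted p = 0.578), and Spdef, a goblet cell transcription factor, at 30.4 ± 3.96 and 23.0 ± 5 (adjusted p = 0.136). The enteroendocrine list had 1 called member of 12, which fell (1 adjusted over the list alone; median -0.37, adjusted p = 0.4), and the deep crypt and antimicrobial list 1 higher and 1 lower of 14 (the same numbers adjusted over the list alone; median -0.31, adjusted p = 0.963). None of 24 cell cycle genes was called, over all genes or adjusted over the list alone (median -0.20, mean -0.15 and a test that pointed up, adjusted p = 0.96, by camera).

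Genes of the non-epithelial wall fell in large numbers. Of 22 fibroblast and matrix genes, 19 fell (21 adjusted over the list alone) and none rose, with a median of -2.16, including Col1a2 (34.2 ± 5.39 to 5.08 ± 4 FPKM), Col1a1 (24.3 ± 6.55 to 3.49 ± 3.38) and Lum (11.5 ± 4.17 to 1.70 ± 0.79). Its adjusted p was 1.57e-13, and adjusted p = 0.41 with an estimated correlation. Of 11 endothelial genes, 9 fell (10 adjusted over the list alone; median -1.25), among them Plvap (25.6 ± 5.76 to 5.40 ± 4.76) and Cdh5 (-1.27), with adjusted p = 7.01e-07, and adjusted p = 0.41 with an estimated correlation. Of 16 smooth muscle genes, 7 fell (15 adjusted over the list alone; median -1.80, adjusted p = 1.92e-05, and adjusted p = 0.459 with an estimated correlation). The myosin light chain kinase gene Mylk fell by 1.83, from 157 ± 83.4 to 43.8 ± 22.7 FPKM, and lost its call without control 3, control 4, DSS 3 or DSS 4 (adjusted p up to 0.0997). Of 16 enteric neuron and glia genes, 2 fell (11 adjusted over the list alone; median -0.84), with Vip, a neuropeptide, at 24.4 ± 8.51 and 3.77 ± 2.04 FPKM (adjusted p = 0.00368). That list had adjusted p = 4.12e-04, and adjusted p = 0.459 with an estimated correlation. None of 12 adipocyte genes was called, over all genes or over the list alone (median -1.12, adjusted p = 0.254), and none of 9 genes of other tissues (median 0.21, adjusted p = 0.254).

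Immune cell lists were lower or not called in DSS, but many of their members were not tested. Untested were 21 of 30 cytokine, 18 of 20 neutrophil, 15 of 22 T and NK cell and 10 of 18 B and plasma cell genes. Il1b, Il6 and Cxcl1 were among these, and a gene high in under 4 libraries fails the filter. These lists therefore cannot show that inflammation was absent. Of 15 monocyte and macrophage genes, 8 fell (9 adjusted over the list alone; median -1.08, adjusted p = 3.74e-05, and adjusted p = 0.41 with an estimated correlation), including the complement genes C1qb (14.9 ± 2.86 to 2.59 ± 1.06 FPKM) and C1qc (-2.06) and the receptor gene Csf1r (-1.42). Of 8 B and plasma cell genes, 4 fell (4 adjusted over the list alone), among them Igha, Jchain and Mzb1 (-1.46), while the list had a median of -0.57 and adjusted p = 0.0687. Of 7 T and NK cell genes, 2 fell (2 adjusted over the list alone; median -0.14, adjusted p = 0.653). Of 9 cytokine genes, 1 fell (1 adjusted over the list alone; median -0.01, positive with median-of-ratios scaling, adjusted p = 0.771): Ccl11, the eosinophil attractant eotaxin (6.84 ± 2.62 to 0.472 ± 0.447 FPKM, adjusted p = 0.00246). Neither of the 2 neutrophil genes tested passed over all genes, Ly6g (2.59, adjusted p = 0.108) and S100a9 (2.05, adjusted p = 0.138), while both were higher adjusted over the list alone. Kit, the only mast cell and eosinophil gene tested, had a log2 fold change of -0.69 (adjusted p = 0.12; lower adjusted over the list alone).

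The FGF signalling, Wnt, interferon and endoplasmic reticulum stress lists fell in DSS and the respiration list rose, beside the fibroblast list at -2.16. Of 24 FGF signalling genes, 7 fell (9 adjusted over the list alone; median -0.40, adjusted p = 0.00217, and adjusted p = 0.41 with an estimated correlation), including the feedback inhibitor Spry4 (2.70 ± 0.374 to 0.684 ± 0.336 FPKM, adjusted p = 0.00378) and the growth factor Fgf7 (-1.04). Fgf1 itself (chromosome 18, 38838673 to 38929472) fell from 8.48 ± 0.98 to 4.95 ± 1.52 FPKM (-0.71 ± 0.20, adjusted p = 0.039), but lost its call on leaving out any of control 1 to control 4, DSS 2, DSS 3 or DSS 4 (adjusted p = 0.0566 to 0.104), while Fgfr2 was at 14.1 ± 3.76 and 10.6 ± 5.01 (adjusted p = 0.347). Of 21 genes of endoplasmic reticulum stress, 5 fell (9 adjusted over the list alone; median -0.33, adjusted p = 0.00217, and adjusted p = 0.41 with an estimated correlation), with Xbp1 at -0.51 and Pdia4 at -0.55. Of 17 Wnt genes, 6 fell (7 adjusted over the list alone; median -0.30, adjusted p = 0.0397, and adjusted p = 0.41 with an estimated correlation), among them the inhibitors Sfrp1 (-1.72) and Dkk3 (-1.81). The Wnt call was lost without control 2 (0.0706), control 4 (0.0636), DSS 2 (0.0684) or DSS 3 (0.0611). With the smooth muscle score as a covariate, which left 29 calls among all genes, Fgf7 (-0.575, adjusted p = 0.258), Spry4 (-0.849, 0.0957), Sfrp1 (-1.05, 0.0733) and Dkk3 (-0.97, 0.162) were not called. Of 28 interferon-stimulated genes, 5 fell (10 adjusted over the list alone, with 1 higher; median -0.40, adjusted p = 0.0207, and adjusted p = 0.528 with an estimated correlation), and the list call was lost without control 4 (0.0947) or DSS 1 (0.287). Of 29 mitochondrial respiration genes, 1 rose (1 adjusted over the list alone), Ndufb8, from 127 ± 5.47 to 179 ± 23 FPKM (adjusted p = 0.0144), with a list median of 0.14 (adjusted p = 5.67e-06, and adjusted p = 0.41 with an estimated correlation). Ndufb8 had a start-event value of -1.43 (adjusted p = 0.577; range over the alternatives 0.00426 to 0.636).

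The remaining lists moved little in DSS. Of 17 junction genes, 1 rose (0 adjusted over the list alone by limma), with a median of 0.06 (adjusted p = 0.0456, and adjusted p = 0.459 with an estimated correlation), a call lost without control 3 (0.147), control 4 (0.0636), DSS 1 (0.0982) or DSS 2 (0.174). Of 23 genes of PPAR targets and lipid handling, the only called member was the fatty acid transporter gene Cd36, which fell by 1.70 (0 adjusted over the list alone), although the list rose by its test (median 0.09, adjusted p = 0.0397, and adjusted p = 0.625 with an estimated correlation). This call was lost without control 3 (0.406), control 4 (0.106), DSS 1 (0.0879) or DSS 4 (0.0845), and that of Cd36 without control 2, control 3, control 4, DSS 2, DSS 3 or DSS 4 (adjusted p = 0.0685 to 0.111). The Notch list (1 of 16 lower, 1 adjusted over the list alone; median -0.18, adjusted p = 0.639) and the fetal-like repair list (1 of 17 higher, 0 adjusted over the list alone; median -0.02, positive with median-of-ratios scaling, mean -0.10 and a test that pointed up, adjusted p = 0.402) were not called.

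In all, limma called 1549 of 12578 genes in DSS against control, 280 higher (18.1%) and 1269 lower. With median-of-ratios scaling it called 677 higher (40.8%) and 982 lower, and the median log2 fold change of all genes moved from -0.0705 to 0.0537, so the balance of directions depends on the scaling. The libraries of both groups did not overlap in 16.9% of genes, against 2.86% by chance, and 14 of 28 lists were called with the preset correlation, 4 higher and 10 lower. Start-event values called 727 genes (684 shared) and 11 lists. Leaving out DSS 3, control 4, control 3 or DSS 4 gave 692, 775, 830 and 832 genes, leaving out DSS 3 and DSS 4 together 168 (157 shared, 14 lists), and leaving out control 3 and FGF1 3 1034. With the smooth muscle score as a covariate 29 genes were called (26 shared), among them Slc9a3, Igha, Clec3b, Dpt and C1qc. Among the genes named above, start-event values ended the calls of Muc2, Lhfpl2, Ndufb8, Zg16 (2.27 before and after), Slc51a (2.00 and 0.683), Mylk (-1.83 before and after), Fgf1 (-0.71 and -0.688) and Pdia4 (-0.55 and -1.82). Leaving out DSS 3 and DSS 4 ended, among others, those of Gsdmc2 (log2 fold change -3.40 before and -3.57 after), Gsdmc3 (-3.17 and -3.39), Gsdmc4 (-4.49 and -4.5), Best2 (2.35 and 2.3) and Muc2 (-1.06 and -1.29), whose differences stayed about as large with fewer libraries, and of Col1a1 (-2.74 and -1.97) and BB123696 (3.61 and 2.88), and not those of Col3a1, Igha, Jchain, Saa3, Slc9a3 and Agr2. The plots of list medians and of list scores by library show the groups described.

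**Figure D2:**
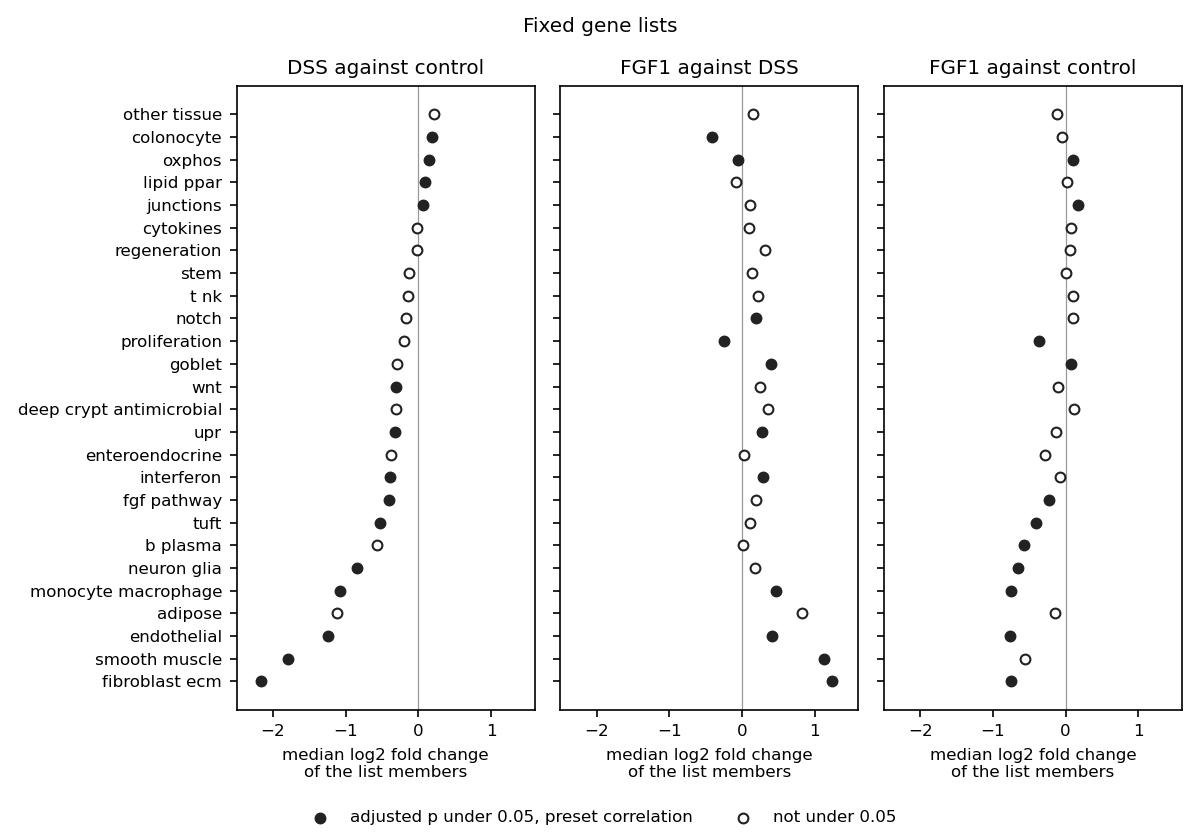
Median log2 fold change of 26 gene lists (vertical axis) in the 3 comparisons (horizontal axis, log2), filled where the adjusted p was under 0.05 with the preset correlation. The fibroblast list lay at -2.16 in DSS against control, 1.24 in FGF1 against DSS and -0.75 in FGF1 against control.

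**Figure D3:**
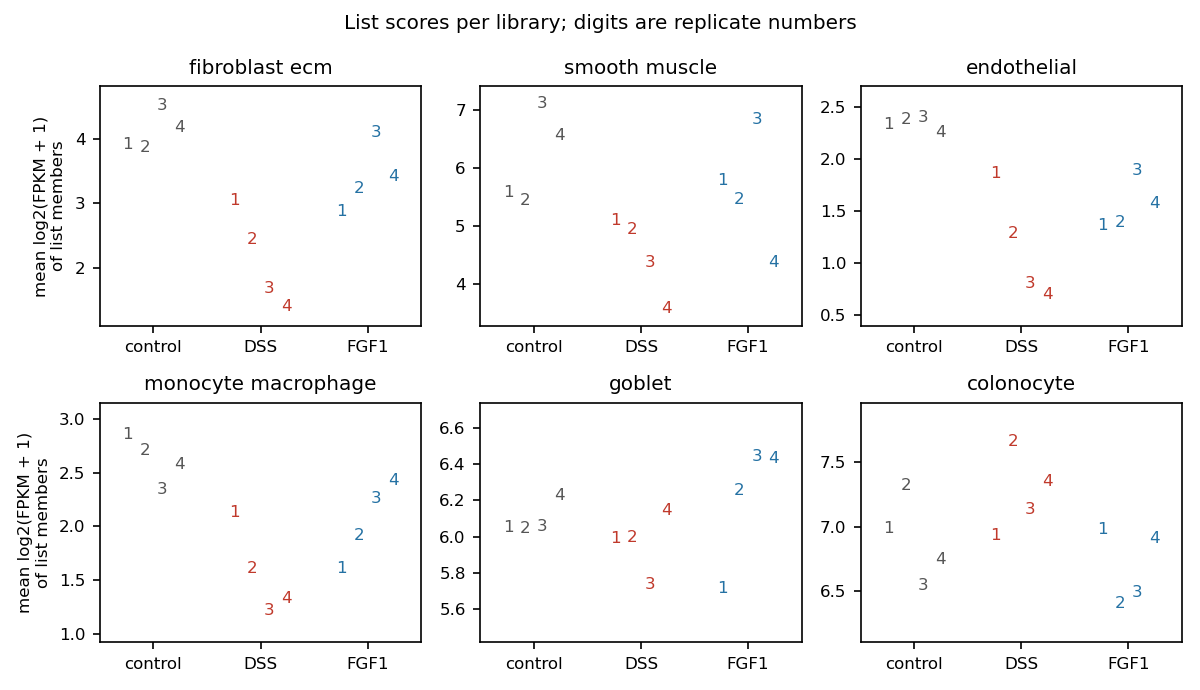
Score of 6 gene lists, the mean log2(FPKM + 1) of the members, in each library, with each library drawn as its replicate number. The fibroblast score was 1.41 to 3.04 in the DSS libraries and 3.87 to 4.51 in the control libraries.

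The comparison of FGF1 with DSS bears on the design's question about supplying FGF1, although the labels do not state that the FGF1 mice received DSS. Slc9a3 fell from 142 ± 46.3 FPKM in DSS to 38.0 ± 5.73 in FGF1 (SD, n = 4 each; -1.83 ± 0.21, SE, adjusted p = 0.0158). Goblet genes stood higher as a list, with a median of 0.40 over 25 genes (adjusted p = 2.14e-04, and adjusted p = 0.53 with an estimated correlation), although none was called over all genes by limma (9 higher adjusted over the list alone). The goblet scores of the groups overlapped, and FGF1 1 (5.713) lay below each DSS library (5.735 to 6.143). Muc2 was at 1988 ± 464 FPKM in DSS and 3352 ± 532 in FGF1, without overlap of the libraries (0.77 ± 0.25, adjusted p = 0.228). Tnpo1, a nuclear import receptor (chromosome 13, 98839019 to 98926384), rose from 2.85 ± 1.79 to 12.2 ± 1.48 (1.86 ± 0.22, adjusted p = 0.0158). The Slc9a3 call ended without FGF1 2 (adjusted p = 0.0711) and with start-event values (-1.22, adjusted p = 0.213; range over the alternatives 0.00567 to 0.213). That of Tnpo1 ended without DSS 4 (0.0882) or FGF1 2 (0.0711), and its start-event value pointed the other way (-0.73, adjusted p = 0.828; range over the alternatives 6.2e-07 to 0.828).

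Of the other called genes of FGF1 against DSS, all but 0610040F04Rik were close to the threshold. St6galnac6, a sialyltransferase gene, rose from 93.7 ± 21.6 to 235 ± 56.8 FPKM (adjusted p = 0.0495), and lost its call without DSS 2, DSS 3, DSS 4, FGF1 1, FGF1 2 or FGF1 3 (0.0557 to 0.147). Shroom2 (0.95) and the potassium channel gene Kcnk6 (0.79) also rose, each with adjusted p = 0.0495, and kept their call only when DSS 1 was the library left out (otherwise 0.0557 to 0.147). Slc19a1, the reduced folate carrier, fell from 10.8 ± 1.94 to 5.61 ± 0.441 FPKM (adjusted p = 0.0495), a call lost without DSS 3, DSS 4 or any FGF1 library (0.0728 to 0.147). 0610040F04Rik, named outside the rule after its values were seen, rose by 1.32 (adjusted p = 0.0197), a call lost without DSS 4 (0.0882), FGF1 2 (0.0724) or FGF1 3 (0.0589). Short of the threshold were Saa1 (1932 ± 645 and 501 ± 69.3 FPKM, adjusted p = 0.0532), Adtrp (40.8 ± 8.64 and 10.1 ± 6.36, 0.0532), Marc2 (-0.63, 0.0539) and Gcnt1 (-0.97, 0.054), with lower values in FGF1. Higher values in FGF1 that did not pass were those of Slc12a8 (20.4 ± 3.23 and 36.4 ± 2.37, 0.054), Ccl9 (0.88, 0.0532), Utp20 (0.90, 0.054), Fam83c (0.94, 0.0539) and Slc9a3r2 (0.83, 0.0539). Fgf1 was at 4.95 ± 1.52 FPKM in DSS and 7.12 ± 1.65 in FGF1 (0.364), and Spdef (0.34, 0.438), Fgfr2 (0.28, 0.719) and Lgr5 (0.25, 0.526) were not called.

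Epithelial lists of FGF1 against DSS differed in direction, although the difference between the goblet and colonocyte scores had overlapping libraries. The goblet members higher adjusted over the list alone were Slc12a8, Creb3l1 (0.72), Agr2 (0.72), Tpsg1, Gfi1, Galnt12, Creb3l4, Muc2 and B3gnt6, whereas Tff3 (-0.75), Zg16 (-0.69), Best2 (-0.50) and Clca1 (-0.45) were among those with lower values. The log2 fold changes of the goblet members ran from -1.66 to 1.42. Of 26 colonocyte genes, 1 fell, Slc9a3 (5 adjusted over the list alone, among them Saa1, Guca2b and Tmigd1), and the list median was -0.41 (adjusted p = 1.52e-07, and adjusted p = 0.53 with an estimated correlation). None of 24 cell cycle genes was called by limma over all genes or adjusted over the list alone, with a list median of -0.24 (adjusted p = 1.93e-04, and adjusted p = 0.624 with an estimated correlation), a list call lost without DSS 1 (0.093). The stem cell list (1 of 18 higher adjusted over the list alone; median 0.13, adjusted p = 0.0693) was not called, nor were the enteroendocrine (0.03, negative with median-of-ratios scaling, adjusted p = 0.456), tuft (0.12, 0.456), deep crypt (0.36, 0.382), junction (0.10, 0.203, 1 higher adjusted over the list alone), PPAR and lipid (-0.09, 0.0536) and repair lists (0.32, 0.973).

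Genes of the wall and of macrophages had higher values in FGF1 than in DSS. Fibroblast genes had a median of 1.24 over 22 genes (adjusted p = 1.6e-13, and adjusted p = 0.53 with an estimated correlation), with Col3a1 at 8.79 ± 7.12 FPKM in DSS and 38.7 ± 17.4 in FGF1, and 17 higher adjusted over the list alone. Smooth muscle genes had a median of 1.12 over 16 genes (adjusted p = 2.27e-05, and adjusted p = 0.624 with an estimated correlation), none of them called adjusted over the list alone. Monocyte and macrophage genes had a median of 0.47 (adjusted p = 0.00536, and adjusted p = 0.624 with an estimated correlation), with C1qb (1.34) and C1qc (1.13) higher adjusted over the list alone. Endoplasmic reticulum stress genes (0.27, adjusted p = 0.0097), interferon-stimulated genes (0.29, 0.0122, with Gbp2 higher adjusted over the list alone), endothelial genes (0.42, 0.0236) and Notch genes (0.19, 0.0352) were called higher, and respiration genes (-0.05, 0.0101) lower. These 5 lists had adjusted p = 0.624 with an estimated correlation, and no member of any list but Slc9a3 was called over all genes. Their calls were lost for macrophages without DSS 3 (0.0934), for stress genes without DSS 1 (0.093) or DSS 3 (0.0715), and for interferon genes without DSS 1 (0.358) or FGF1 4 (0.197). Those of endothelium were lost without DSS 3 (0.126), DSS 4 (0.248) or FGF1 3 (0.0942), those of respiration without DSS 3 (0.41), DSS 4 (0.12) or FGF1 3 (0.0942), and those of Notch without DSS 2 (0.109), DSS 3 (0.0718), DSS 4 (0.0622), FGF1 1 (0.0708) or FGF1 2 (0.0877). Not called were cytokines (0.09, adjusted p = 0.255, 1 higher adjusted over the list alone), T and NK cells (0.22, 0.603), B and plasma cells (0.02, negative with median-of-ratios scaling, 0.456, with Igha higher adjusted over the list alone), neurons and glia (0.18, 0.456), adipocytes (0.82, 0.131), FGF signalling (0.19, 0.211) and Wnt (0.25, 0.136). The other-tissue list had a median of 0.15, a mean of -0.83 and a test that pointed down (adjusted p = 0.382), with 1 higher and 4 lower adjusted over the list alone. The neutrophil median was -0.96 over 2 genes and Kit stood at 0.53.

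Limma called 7 genes in FGF1 against DSS, 5 higher (71.4%) and 2 lower, and 1561 had an unadjusted p under 0.05; median-of-ratios scaling gave 8 higher (53.3%) and 7 lower. Libraries did not overlap in 6.3% of genes, against 2.86% by chance. Start-event values called 1 gene, none of the 7, and 7 lists instead of 11. Leaving out a library gave 43 genes (DSS 1), 1 (DSS 4), 3 (FGF1 1) or 0 (FGF1 2, where limma left 1291 at an unadjusted p under 0.05), and 6 lists without DSS 3. Leaving out DSS 3 and DSS 4 gave 0 genes by limma (1161 unadjusted), and leaving out control 3 and FGF1 3 gave 2. The smooth muscle covariate gave 0 (1280 unadjusted).

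The comparison of FGF1 with control shows which differences from untreated colon were present in FGF1. The plasma cell transcripts Igha (1050 ± 646 FPKM in control, 265 ± 163 in FGF1, SD, n = 4 each) and Jchain (194 ± 100 and 28.4 ± 22.2) did not pass over all genes and were lower adjusted over their list alone. Ccl11 fell from 6.84 ± 2.62 to 0.798 ± 0.586 FPKM (-2.11 ± 0.30, SE, adjusted p = 0.0385), and Nr1d2, a clock repressor, rose from 4.37 ± 1.02 to 12.1 ± 1.76 (1.3 ± 0.19, adjusted p = 0.0385). Muc2 was at 4169 ± 1200 in control and 3352 ± 532 in FGF1 (adjusted p = 0.663), Col3a1 at 66.8 ± 13.7 and 38.7 ± 17.4, and Slc9a3 at 29.9 ± 5.35 and 38.0 ± 5.73. Nr1d2 was called only when FGF1 3 was the library left out, with adjusted p = 0.0607 to 0.157 otherwise, and Ccl11 lost its call without control 1, control 2, FGF1 1, FGF1 2 or FGF1 4 (0.0817 to 0.157).

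The other called genes all fell. They were Iyd, an iodotyrosine deiodinase (-0.84, adjusted p = 0.0458), Scgn, a calcium-binding protein of endocrine cells (-0.97, 0.0385), the macrophage lectin gene Mgl2 (-0.998, 0.0385) and C1qtnf3 (-1.21, 0.0385). The immunoglobulin segments, named outside the rule after their values were seen, were Ighv2-2 (-2.16, 0.00261), Ighv1-9 (-2.06, 0.0385), Igkv1-110 (45.9 ± 18.6 to 8.26 ± 5.79 FPKM, 0.0385) and Ighv1-22 (-2.88, 0.0458). Of the 12 libraries, 5 listed Ighv2-2 at 0, 3 Ighv1-9, 4 Ighv1-22 and 1 Mgl2. Ighv2-2 kept its call whichever library was left out. The calls of Iyd, Scgn, C1qtnf3 and Igkv1-110 ended on leaving out any library of control or FGF1 except FGF1 3. Those of Mgl2 and Ighv1-22 ended likewise except for control 3 and FGF1 3, and that of Ighv1-9 except for control 4 and FGF1 3 (adjusted p for these genes 0.0564 to 0.17). Values that did not pass were those of Clca4b (1.34 ± 0.354 and 25.6 ± 9.11 FPKM, adjusted p = 0.054), Dbp (2.53 ± 0.567 and 11.5 ± 3.12, 0.054), Lama3 (1.3, 0.066), Mvd (0.71, 0.0504) and Pycard (0.52, 0.0706), higher in FGF1. Lower were Clec3b (-1.93, 0.0554), Hsd11b1 (-1.33, 0.0564), Adgra2 (-1.19, 0.066), Ppm1l (-0.82, 0.0689) and Cox6b2 (-0.73, 0.066). Lgr5 was at 1.28 ± 0.238 and 1.98 ± 0.238 FPKM (0.261), and Fgf1 (-0.24, 0.644), Fgfr2 (-0.15, 0.86) and Spdef (-0.07, 0.906) were not called.

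Among lists, endothelial, fibroblast, nerve, tuft and plasma cell genes were lower in FGF1 than in control, while the smooth muscle list was not called. Endothelial genes had a median of -0.76 (adjusted p = 3.06e-07, and adjusted p = 0.618 with an estimated correlation; 10 of 11 lower adjusted over the list alone). Tuft genes had -0.41 (1.38e-04; 1 of 13, Rgs13 at -0.62) and B and plasma cell genes -0.57 (0.0193; 4 of 8, including Jchain at -3.03 and Igha at -2.04), both adjusted p = 0.618 with an estimated correlation. Without control 1 the plasma cell list had 0.0918. Fibroblast genes had a median of -0.75 (5.03e-05; 22 tested, none adjusted over the list alone), neurons and glia -0.65 (5.69e-05; 1 of 16, Vip at -1.82), macrophages -0.75 (3.88e-04; 4 of 15) and FGF signalling -0.23 (0.002; 6 of 24, including Spry4 at -0.82 and Fgf7). These 4 lists had adjusted p = 0.628 with an estimated correlation. Cell cycle genes had a median of -0.37 (7.57e-04, and adjusted p = 0.657 with an estimated correlation; none of 24 adjusted over the list alone). Higher were junction genes (0.17, 5.69e-05, and adjusted p = 0.618 with an estimated correlation; 1 of 17 adjusted over the list alone, Pkp3 at 0.57), respiration genes (0.10, 3.8e-04; none of 29) and goblet genes (0.08, 0.0417; Best2 higher and Clca1 lower of 25), the last pair adjusted p = 0.628 with an estimated correlation. The goblet call was lost without control 1 (0.156), control 3 (0.117), FGF1 2 (0.12), FGF1 3 (0.145) or FGF1 4 (0.0509). Over all genes, Ccl11 was the only called list member.

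Lists not called in FGF1 against control were stem cells (median 0.01, adjusted p = 0.592, 1 lower adjusted over the list alone), enteroendocrine cells (-0.28, 0.729), deep crypt (0.12, 0.422), smooth muscle (-0.56, 0.0682), adipocytes (-0.15, 0.976), Notch (0.11, 0.227), Wnt (-0.11, 0.159, 4 lower adjusted over the list alone), interferon (-0.08, 0.549), stress (-0.13, 0.126), repair (0.05, 0.231) and cytokines (0.08, 0.506, 1 higher and 1 lower adjusted over the list alone). Sign differed between median, mean and test for colonocytes (-0.04, positive with median-of-ratios scaling, -0.20 and up, adjusted p = 0.807), T and NK cells (0.10, -0.13 and down, 0.823), PPAR and lipid genes (0.02, -0.06 and up, 0.506) and other tissues (-0.12, -0.14 and up, 0.52). The neutrophil median was 1.36 over 2 genes and Kit stood at -0.16.

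Limma called 10 genes in FGF1 against control, 1 higher (10%) and 9 lower, with 1753 at an unadjusted p under 0.05; median-of-ratios scaling gave 7 higher (46.7%) and 8 lower. Libraries did not overlap in 10.3% of genes, against 2.86% by chance, and 11 lists were called. Start-event values called 1 gene, Ighv2-2, and 11 lists. Leaving out a library gave 2 genes (control 1), 1 (control 2), 3 (control 4), 2 (FGF1 1), 1 (FGF1 2), 83 (FGF1 3) and 2 (FGF1 4). Leaving out control 3 and FGF1 3 gave 38, and a mean of at least 5 FPKM gave 0 by limma (840 unadjusted).

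The FGF1 and DSS comparisons share the DSS libraries, and all 7 genes called in FGF1 against DSS were called the opposite way in DSS against control. Slc9a3 went 2.17 and then -1.83, Slc19a1 0.84 and -0.82, Tnpo1 -1.93 and 1.86, St6galnac6 -1.19 and 1.31, Shroom2 -0.86 and 0.95, Kcnk6 -0.63 and 0.79, and 0610040F04Rik -0.90 and 1.32. None was called the same way in both. Independent lists of these sizes would share 0.504 genes that fell and then rose and 0.045 that rose and then fell. The shared DSS libraries make both lists dependent, so these numbers are no reference for the 7 genes. Simulated unchanged groups shared 0 in 100 draws, which is no reference either, since no gene was made to change there. The fold changes of both comparisons had a covariance over genes of -0.136, against -0.029 on average in the simulation (range -0.137 to 0.016, with 1 draw as low), a difference of -0.107. Their correlation was -0.739 (simulated mean -0.425, 17 draws as low), and genes are not independent replicates. With the DSS libraries split so that each comparison used its own pair, the covariance was -0.114 to -0.069 and the genes called both ways numbered 0 to 45. With start-event values 1 gene was called both ways and the covariance was -0.212.

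Exon use was compared in 2224 skipped-exon events of 1658 genes. In FGF1 against DSS limma called 5. The included share of an exon of Chd2, a chromatin remodeller (chromosome 7, 73454691 to 73454803), was 0.34% in DSS and 58.1% ± 38.3 in FGF1 (4.23 ± 0.63 as a log2 ratio). That of Trim26 (chromosome 17, 36854284 to 36854301) was 48.9% ± 4.62 and 1.22% ± 1.75 (-4.73 ± 0.72), that of Prpsap2 (chromosome 11, 61755410 to 61755462) 24.3% and 85.1%, that of Wdr45 (chromosome X, 7723315 to 7723753) 1.22% and 30.8%, and that of Fam241b (chromosome 10, 62110236 to 62110314) 26.6% and 71.8%, each with adjusted p = 0.0265. No event kept its call through the omissions: Fam241b, Trim26 and Wdr45 lost it whichever of the 8 libraries was left out, and Chd2 and Prpsap2 for all but FGF1 1 (adjusted p = 0.0573 to 0.107). Limma called 0 events in DSS against control (181 at an unadjusted p under 0.05) and 0 in FGF1 against control (106). It called 0 of 1041 retained introns (81, 62 and 44 unadjusted in DSS against control, FGF1 against DSS and FGF1 against control), 0 of 7132 start sites (576, 420 and 342) and 0 of 3173 end sites (301, 233 and 153). A Chd2 start site (chromosome 7, 73468456 to 73468587) moved like the Chd2 exon, with a share of 0.332% in DSS and 54.8% ± 36.3 in FGF1 (limma, adjusted p = 0.0927). For Chd2, exon inclusion and a change of start site cannot be told apart. In data simulated for DSS against control, 22.9% of 4-fold exon changes were found, so most changes of that size may have gone undetected.

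The number of listed events was lower in DSS than in control for all 12 event types, with 12703 ± 286 skipped exons in control and 11095 ± 1140 in DSS (SD, n = 4 each; -12.7%). Of the 36 exact permutation tests (two-sided) none passed after adjustment. In DSS against control 5 types reached the smallest possible exact p (0.0286, adjusted 0.114), and FGF1 had fewer events than control in 12 types, 4 of them at 0.0286. Against DSS the lowest adjusted p in FGF1 was 0.374.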

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

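The search for libraries standing apart was planned, and the genes searched are those that the rule for named genes selects, with the called genes added to it. The counts over other splits of the samples were planned too. Of 474 sets of 4 values, 36 (7.6%) had a library whose gap to its nearest neighbour, as a share of the set's range, exceeded Dixon's critical value for 4 values. For independent, normally distributed values chance does so in about 1 in 20 sets. Gene values were searched as FPKM without logarithm, and genes vary together. The 7.6% therefore cannot be set against that rate.

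DSS 1 stood highest within DSS for Tnpo1 (5.53 FPKM against 2.04 in the next library, share 0.937), Clca4b (28.1 against 5.63, 0.856), Cd36 (0.853), Mrc1 (0.838), C1qc (0.882), Mvd (0.847) and Shroom2 (0.833), and for the Notch score (2.96 against 2.66, 0.8291). It was the only DSS library above 0 for Ighv1-9 and for Ighv2-2 (share 1 each). The 10 most abundant genes held 7.5% of its FPKM, the lowest in DSS (0.867). DSS 2 stood highest for Jchain (15.9 against 4.85 FPKM, 0.91) and Igkv1-110 (0.843), DSS 4 for Slc51a (147 against 83.3, 0.892), and DSS 3 was the only DSS library above 0 for Ighv1-22 (1).

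FGF1 3 stood highest within FGF1 for Dpt (29.0 against 14.2 FPKM, 0.96), Ang4 (72.0 against 24.8, 0.896), Sfrp1 (0.882), Dkk3 (0.865), Slc9a3r2 (0.919), Scgn (0.918), Igkv1-110 (0.831) and the endoplasmic reticulum stress score (0.861). FGF1 2 was highest for Ighv1-9 (0.904) and FGF1 4 for Xbp1 (0.868), while FGF1 4 was lowest in the adipocyte score (2.21 against 4.03, 0.872) and FGF1 1 in the cytokine score (0.857).

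Control 1 stood highest within control for Igha (2016 against 804 FPKM, 0.909), Jchain (343 against 156, 0.861) and Pdia4 (0.935), and lowest in the mast cell and eosinophil score (0.921). Control 3 was highest for Fgf7 (0.918) and Col1a2 (0.846) and lowest for Marc2 (0.889). Control 4 was highest for Saa1 (980 against 460 FPKM, 0.858) and in the goblet score (0.92).

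Other splits of the 8 libraries of a comparison, 35 in all with the real split, bear on whether chance can be excluded. The real split gave 1549 genes in DSS against control (highest other split 1), reached by 1 of 35 splits, the smallest share possible. The other splits mix libraries of both groups, so a real difference widens the spread within their groups and lowers their counts. Counts of 7 genes in FGF1 against DSS (highest other 2), 10 genes in FGF1 against control (3), and 11 lists (10) and 5 exon events (4) in FGF1 against DSS were each reached by 1 split too. For all these counts, the 1549 genes included, 1 split is limited evidence against chance, since the share is not adjusted for the number of counts compared. The 7 genes became 0 without FGF1 2 and the 10 became 1 without control 2, 0 lists were called with an estimated correlation, and each exon event lost its call in 7 or 8 of 8 omissions. For the reversal, in which control kept its place and each split counted with the larger of its 2 assignments, the real split gave 7 genes (highest other 2), reached by 1 of 35 splits. No other split called more than 2 genes in FGF1 against DSS, so none could have reached 7 and this count says nothing of its own on chance. Chance cannot be excluded for the number of lists in DSS against control (14, highest other 15, reached by 3 splits) or in FGF1 against control (11, highest other 15, reached by 8). The counts of 0 were reached by all 35 splits, with highest others of 2 for exon skipping in DSS against control and in FGF1 against control, 1, 2 and 2 for intron retention, 5, 5 and 6 for start sites and 4, 5 and 5 for end sites.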

How the results depend on the processing

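Chosen after the data were seen were the start-event and common-transcript values, the genes with 1 annotated transcript, the smooth muscle covariate and the fits that leave aside a pair of libraries; the rest was planned. Results are counts of genes called by limma, in the order DSS against control, FGF1 against DSS and FGF1 against control (1549, 7 and 10), and the cause of a change was not tested unless given. Of the named genes' values under the alternatives, 1529, 387 and 401 kept direction and side of the threshold, 399, 89 and 124 lost the call, 3, 36 and 51 gained it and 7, 5 and 7 changed sign. For lists 158, 115 and 134 values held, 38, 37 and 20 lost the call, and 2 in FGF1 against DSS changed sign. For the exon events of FGF1 against DSS 7 held and 44 lost the call.

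Start-event values gave 727, 1 and 1 genes, 7 lists in FGF1 against DSS, 1 reversed gene and a covariance of -0.212. The sign turned for Lhfpl2 (-0.76), Ndufb8 (-1.43), Spdef (0.628) and Etv5 (0.303) in DSS against control, Tnpo1 (-0.729) and Spdef (-0.147) in FGF1 against DSS and Spdef (0.481) in FGF1 against control. Start events are missing for some transcripts of a library, so these sums also move with what was listed: the median within-group SD was 0.305, against 0.239 for the transcript sums. End events gave 708, 1 and 3 genes, with Fgfr2 at 0.553, Rgs13 at 0.975 and Thy1 at 0.999 in DSS against control, Fgfr2 at -0.414 and Marc2 at 1.1 in FGF1 against DSS, and Lama3 at -0.278 and Fgfr2 at 0.139 in FGF1 against control. Transcripts listed in all 12 libraries gave 922, 4 and 1 genes and Lama3 at -0.278, and genes with 1 annotated transcript, of which fewer are tested, gave 233 in DSS against control and 29 in FGF1 against control.

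A mean of at least 5 FPKM gave 564, 16 and 0 genes (840 at an unadjusted p under 0.05 in the last), no filter 50 in FGF1 against control, and a pseudocount of 0.1 gave 0 there (1609 unadjusted), a covariance of -0.284 and 1 end site each in DSS against control and FGF1 against control. Median-of-ratios scaling gave 15 genes in FGF1 against DSS, 13 reversed genes and Spdef at 0.00431 in FGF1 against control. Scaling to the same sum gave 3 in FGF1 against DSS and 20 in FGF1 against control, sample weights 56 and 708, and only the 8 samples compared 3 and 38. A mean of at least 20 FPKM gave 1 exon event. With an estimated correlation 0, 0 and 0 lists were called by camera.

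The smooth muscle covariate gave 29, 0 and 2 genes, with 1280 at an unadjusted p under 0.05 in FGF1 against DSS; the score itself was lower in DSS, so the covariate takes up part of the group difference. Without DSS 3 and DSS 4, 168, 0 (1161 unadjusted) and 38 genes and 0 reversed genes were called, Fgfr2 was at -0.119 in FGF1 against DSS, and the endothelial and respiration lists turned direction (adjusted p = 0.77 and 0.275). Without control 3 and FGF1 3, 2 and 38 genes were called in FGF1 against DSS and FGF1 against control, with 1 reversed gene and a covariance of -0.102. With the DSS libraries divided between the comparisons, the reversed genes and the covariance were 45 and -0.114 (DSS 1 and DSS 2 against control), 2 and -0.088 (1 and 3), 1 and -0.109 (1 and 4), 1 and -0.114 (2 and 3), 3 and -0.103 (2 and 4) and 0 and -0.069 (3 and 4).

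Leaving out each library gave 692 to 1998, 0 to 43 and 1 to 83 genes, and 10 to 14, 6 to 13 and 10 to 12 lists. Exon skipping gave 0 to 2, 0 to 4 and 0 to 2 events, intron retention 0 to 3, 0 to 3 and 0 to 1, start sites 0 to 7, 0 to 3 and 0 to 3, and end sites 0 to 0, 0 to 1 and 0 to 3. Spdef in FGF1 against control ran from -0.146 to 0.0263, positive without control 2 (0.0128) or FGF1 4.

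The replicate numbers as a block gave 1028, 2 and 1 genes and 0 exon events in FGF1 against DSS. Same-numbered samples correlated at -0.192 to -0.068 between DSS and control, -0.217 to 0.119 between FGF1 and DSS and -0.073 to 0.399 between FGF1 and control. Of 4 samples, 0, 1 and 2 correlated best with their own number. These values give no sign of a pairing between DSS and control. Between FGF1 and control the highest value of differently numbered samples was 0.257. With 4 same-numbered pairs per comparison, a pairing cannot be excluded.

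Depth is known only as an implied 16700000 to 22800000 fragments, so no counting error can be set on an FPKM. This limits what can be said of genes near 1 FPKM and of the forms of an event, and a value of 0 cannot be read as absence.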

Other observations

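The clock genes and the neutrophil and haemoglobin genes were looked at after their values were seen, and the tests of tissue share, of plasma genes beyond fibroblasts, of epithelial share and of a goblet shift were chosen after the results they bear on; the other tests were planned before their results. Of 15 clock genes, limma called 6 in DSS against control and 1 in FGF1 against control. In DSS against control it called Nr1d2 (4.37 ± 1.02 to 12 ± 3.39 FPKM, SD, n = 4 each; log2 fold change 1.26, adjusted p = 0.00368), Nr1d1 (4.56 ± 0.594 to 11.8 ± 4.76, 1.14, 0.0123), Ciart (0.76, 0.026), Dbp (0.99, 0.0475) and Per3 (0.79, 0.0482) higher and Arntl, an activator of the opposite phase, lower (19.2 ± 2.5 to 10.1 ± 4.05, -0.93, 0.02). In FGF1 against control Nr1d2 rose by 1.3 (adjusted p = 0.0385), while Nr1d1 (1.09, 0.0988), Ciart (0.89, 0.0943), Dbp (1.80, 0.054) and Arntl (-0.69, 0.199) did not pass. Among those that passed in neither were Clock, Cry1, Cry2, Hlf, Nfil3, Npas2, Per2 and Tef, with Hlf at -0.51 and Per2 at -0.23 in DSS against control. Between FGF1 and DSS, Nr1d2 (0.04, adjusted p = 0.961) and Nr1d1 (-0.04, 0.961) were not called.

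Neutrophil and other-tissue scores were highest in DSS 1 and DSS 3. The neutrophil score was 5.56 in DSS 1 and 4.05 in DSS 3, against 1.11 in DSS 2, 0.866 in DSS 4, 0.045 to 1.18 in control and 1.12, 2.67, 1.44 and 2.53 in FGF1 1 to FGF1 4. Ly6g averaged 1.71 ± 2.04 FPKM in control and 29.8 ± 39.7 in DSS (adjusted p = 0.108), and Hbb-bs 13.7 ± 9.04 and 89.0 ± 91.8 (adjusted p = 0.201), so none passed by limma. The score of the other-tissue list, which holds the haemoglobin genes, was 4.26 in DSS 1 and 4.08 in DSS 3, against 2.89 in DSS 2, 2.52 in DSS 4, 2.45 to 3.1 in control and 2.22 to 2.85 in FGF1. Of the 1549 genes called in DSS against control, 1439 (92.9%) had an FGF1 mean between those of control and DSS, 52 lay beyond DSS and 58 beyond control. The median share of the DSS difference left in FGF1 was 0.53, as a description, since the comparison shares its libraries.

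Fibroblast, vessel, muscle, nerve and macrophage genes were lower together in DSS than in control. The fibroblast median was -2.17 over transcripts listed in all 12 libraries and -2.04 with median-of-ratios scaling, so neither listing nor scaling accounts for it. A smaller share of non-epithelial tissue in the DSS samples, with an unchanged make-up, would lower the lists alike only if epithelium held none of their RNA. Whether it did was not tested. The fibroblast list score lay -0.62 ± 0.102 (SE) beyond the mean of the 5 lists (second score -0.79 ± 0.162), without overlap in either score (exact permutation p = 0.0286, the smallest possible, 1 of 5 lists tested). The fall was thus not alike, but this does not decide whether such a share was the whole cause. Igha and Jchain lay -2.41 ± 0.683 beyond the fibroblast list without overlap (exact permutation p = 0.0286), but -1.97 ± 0.792 with overlap in the second score (exact permutation p = 0.0571). The log2 fold change of Jchain ran from -5.06 to -1.29 over the alternatives, and the whole B and plasma cell list averaged -1.34 against -1.97 for fibroblasts. For plasma cells the share and a change in the cells therefore cannot be told apart. A smaller share stays open as the whole or a part of the cause. So does a dissection that took other layers of the wall, which was not tested and need not move the lists alike (smooth muscle scored 5.44 in control 2 and 7.12 in control 3, endothelium 2.38 and 2.40). A change of connective tissue under DSS was not tested apart from them.

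The higher Nr1d1, Nr1d2, Ciart and Dbp in DSS and FGF1 may come from another hour of collection than in control, which the labels do not give. Scaling is argued against, since the 4 genes averaged 1.23 with median-of-ratios scaling. A score of other clock outputs minus genes of the opposite phase was higher by 0.65 ± 0.177 (SE, exact permutation p = 0.0303), but the groups overlapped, with DSS 4 (-1.91) below each control library (-1.84 to -1.56). It was 0.84 in FGF1 (exact permutation p = 0.0286) and 0.45 in DSS (exact permutation p = 0.2). The hour and an effect of treatment on the clock cannot be told apart, because each group may have been collected at its own hour.

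Goblet genes stood higher in FGF1 than in DSS by their list median, the direction the design's question concerns. The list scores overlapped, at 5.713, 6.254, 6.443 and 6.433 in FGF1 1 to FGF1 4 and 5.991, 5.997, 5.735 and 6.143 in DSS 1 to DSS 4. The list median was 0.34 with median-of-ratios scaling and 0.43 over transcripts listed in all 12 libraries, so neither scaling nor listing accounts for the higher median. A larger epithelial share in FGF1 would lower wall genes and raise colonocyte genes, but the fibroblast median was 1.24 (17 of 22 higher and none lower adjusted over the list alone), that of smooth muscle 1.12 and that of colonocytes -0.41 (5 of 26 lower and none higher), which argues against this share. A shift from absorptive toward goblet genes in FGF1 is a hypothesis, tested by the goblet minus colonocyte score, which was higher by 0.82 ± 0.314 (SE; second score 0.89 ± 0.357) with overlapping libraries (exact permutation p = 0.0857 and 0.0571), so these 8 libraries leave it open.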
